A study of Homo sapiens with 12 samples.

How the data were processed

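RNA levels were measured in MOLM-16 and SU-DHL-1 cells in 12 libraries, 2 per group. Per the labels, cells received DMSO (0.05% v/v), 1000 nM SD36 or 1000 nM SD36Me for 8 h or 24 h. Total RNA was purified with RNeasy columns, samples with an RNA integrity number of at least 8 were depleted of ribosomal RNA with Ribo-Zero, and libraries were made with the TruSeq RNA v2 kit, per the sample descriptions. Whether the strand of the RNA was used is not given in the sources used here. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17.1.14 and reads were aligned with Bowtie 0.12.8 to GRCh38.p5. The counting tool, the annotation release, the gene filter and the normalization are not given in the sources used here. The series text calls the replicates independent biological replicates. Nothing says that they were separate cultures.

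The deposited values of each line are in log2: log2(x + 1) of a level x per gene and library. The level x is not named in the sources used here. It acts like reads scaled by library, since low values of short RNAs move in steps: outside the reference libraries 75% to 83.5% of 114 to 171 such RNAs stood at small whole ratios to the line's first DMSO library, against 0.8% to 5.5% after random shifts. These ratios cannot show whether x is also scaled by gene length, which cancels between libraries. Other genes were not examined for steps. The plan, written before the data were examined, allowed for counts or for CPM, TPM, RPKM or FPKM values, and the second branch was followed. All 12 sample columns were used, and 0 were left aside. The name of 1 SU-DHL-1 DMSO column has 1 extra digit against its label; it was mapped to DMSO 24 h replicate 1, the only sample left for it. The tables hold 13608 genes for MOLM-16 and 13401 for SU-DHL-1, with 76 and 62 values at 0. Of their gene IDs, 13411 and 13148 were found in GENCODE release 29 on GRCh38, which gave coordinates, strands and exon overlaps. The sets of genes in the tables differ between the lines and were taken as deposited.

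Absolute depth cannot be read from these values. Relative depth was estimated from the smallest steps of short RNAs, as the value of 1 read in each library against the line's first DMSO library. Precision is therefore given as standard errors and 95% confidence intervals over the 2 libraries per group, with variances pooled over the 3 groups of a line.

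Differences were tested with limma 3.58.1 in R 4.3.3, with a variance trend, on log2(x + 1), 1 fit per line over its 6 libraries. Genes with a mean x of at least 1 in a group of the line were tested (13592 in MOLM-16 and 13375 in SU-DHL-1). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes are those of limma. In MOLM-16 the comparisons were SD36 at 8 h with DMSO at 8 h, SD36 at 24 h with DMSO at 8 h, and SD36 at 24 h with SD36 at 8 h. In SU-DHL-1 they were SD36 with DMSO, SD36Me with DMSO, and SD36 with SD36Me, all at 24 h. The difference between the lines was planned for counts only and was not tested.

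Gene lists were written before the data were examined, 38 in all. Each with at least 5 measured genes was tested with the camera function of limma at its preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with a correlation estimated from the data, with fry for shifts in one direction, and on lists without the genes they share. Each fit left 3 residual degrees of freedom for the estimated correlation, so a list that did not pass with it may still have shifted. Members were also tested with p-values adjusted over the list alone. The sign of a list's test can differ from that of its median.

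Genes named in the text were taken by a rule fixed in advance. Part (a) holds the STAT family and CRBN. Part (b) holds, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean x of at least 5 in the higher group, every library of 1 group above every library of the other, and a symbol that is not a clone name. Part (c) holds up to 4 measured members per list with the smallest adjusted p. A gene named in 1 comparison may be given in the others. Any other gene is said to be chosen after its values were seen. Some genes that the rule selects are not reported here.

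Agreement between effects was measured by Pearson correlation and covariance across genes and by the overlap of calls in each direction, beside the product of both counts over the number of genes. Where effects share DMSO libraries, 100 simulations of groups without change against the same controls estimated what sharing alone produces if no gene changes. Each effect was also taken against a different DMSO library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.

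The steps were tested on simulated data in which 200 random genes were changed. For MOLM-16 at 8 h (13592 genes), 25.4% of changes of 0.5 on the log2 scale, 97% of changes of 1 and 100% of changes of 2 were called. For SD36Me in SU-DHL-1 (13375 genes) the shares were 70.1%, 98.5% and 100%. Unchanged genes were called too. In MOLM-16 these numbered 17, beside 17, 65 and 66 changed genes called at the respective sizes. In SU-DHL-1 they numbered 24, beside 47, 66 and 66. In each simulation unchanged genes made up a larger share of the calls than the threshold on adjusted p is meant to allow. Smaller changes than 0.5 were not simulated.

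The alternatives were a pseudocount of 0.1, no filter on level, a mean of at least 5, the compared groups alone, a block for the replicate number, a log2 fold change of at least 1, and leaving out each library in turn. Quantile normalization, rescaling by median ratios, rescaling to equal sums without small structural and mitochondrial RNAs, and limma without the variance trend were added after the data were seen.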

Results

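RNA levels were compared in 2 human cell lines treated with SD36, a compound made to degrade STAT3. MOLM-16 is an acute myeloid leukemia line. SU-DHL-1 is an anaplastic large cell lymphoma line that carries the NPM1-ALK fusion. MOLM-16 was sampled with DMSO at 8 h and with 1000 nM SD36 at 8 h and 24 h. SU-DHL-1 was sampled at 24 h with DMSO, 1000 nM SD36 or 1000 nM SD36Me, a related compound. Each of the 6 groups had 2 libraries, and all means ± SD below are of n = 2 libraries on the linear scale x of the deposited log2(x + 1) values. Absolute depth is not given in the sources used here. Relative depth, read from the steps between the lowest values, lay between 0.848 and 1.104 in MOLM-16 and between 0.875 and 1.281 in SU-DHL-1, each against the line's first DMSO library. These are rough estimates, since 7 to 21 RNAs per library sat at the chosen ratio, and its score was at the least 15.2 against 13.2 for the next ratio (SD36 8 h replicate 2 of MOLM-16). Fold changes were taken on the log2(x + 1) scale, which understates them for genes of low level. Gene IDs and coordinates are those of GENCODE release 29 on GRCh38.

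With MOLM-16, mitochondrial rRNA took 13.4% of the summed values in DMSO replicate 1 and 6.36% in SD36 24 h replicate 2, against 9.75% to 11% in the other libraries of the line. RN7SK, a small nuclear RNA that holds back transcription elongation, took 9.87% to 13.1% in MOLM-16 and 2.84% to 4.96% in SU-DHL-1. Libraries of 1 group correlated at 0.9873 to 0.9957. SD36 8 h replicate 2 of MOLM-16 correlated more closely with SD36 24 h replicate 1 (0.9884) than with its own replicate (0.9873). Of the genes tested, those with every library of 1 group above every library of the other made up 46.8% at 8 h and 61.1% at 24 h against DMSO in MOLM-16. In SU-DHL-1 the share was 80.1% with SD36 and 46.5% with SD36Me, where chance gives 33.3%. The p-values measure the spread between these libraries. The series text calls the replicates independent biological replicates, and nothing says that they were separate cultures.

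STAT3 itself (ENSG00000168610.14, chromosome 17, 42313324 to 42388568, minus strand) encodes the transcription factor that SD36 targets. In SU-DHL-1 its RNA fell with SD36 from 207 ± 0.347 to 92.7 ± 0.941, log2 fold change -1.15, SE 0.040, adjusted p = 1.34e-06. With SD36Me it stood at 191 ± 4.30, a log2 fold change of -0.11 (95% CI -0.21 to -0.020) that did not pass the test (adjusted p = 0.292). In MOLM-16 STAT3 fell at 8 h from 87.8 ± 0.237 to 57.4 ± 4.37, log2 fold change -0.61, SE 0.12, adjusted p = 0.0266. That call ended without any single library of the pair of groups: adjusted p = 0.102 and 0.0674 without DMSO replicates 1 and 2, and 0.0832 and 0.0591 without SD36 8 h replicates 1 and 2. At 24 h STAT3 stood at 68.6 ± 4.27 (log2 fold change -0.35, adjusted p = 0.0848), and it passed after quantile normalization (0.0407), rescaling by median ratios (0.0353) or rescaling without small structural and mitochondrial RNAs (0.0251). No protein was measured here.

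Among the other STAT genes of SU-DHL-1, STAT4, which relays interleukin-12 signals, rose from 3.37 ± 0.0163 to 12.8 ± 0.464, log2 fold change 1.66, SE 0.062, adjusted p = 1.85e-06. STAT6, the interleukin-4 mediator, rose from 36.2 ± 1.03 to 56.8 ± 1.06 (0.64, adjusted p = 4.68e-05), and STAT5B fell from 42.2 ± 1.71 to 29.3 ± 0.283 (-0.51, adjusted p = 0.000161). STAT2 (-0.11, adjusted p = 0.0905) did not pass, though it passed as lower after rescaling by median ratios (adjusted p = 0.00323). In MOLM-16 at 24 h STAT2 rose (log2 fold change 0.48, adjusted p = 0.0404). This did not hold without DMSO replicates 1 or 2 (0.189 and 0.0667), without SD36 24 h replicates 1 or 2 (0.175 for each), after rescaling without small structural and mitochondrial RNAs (0.0537) or without the variance trend (0.0548). CRBN (ENSG00000113851.13, chromosome 3, 3144628 to 3179727, minus strand), which encodes the substrate receptor of the cereblon ubiquitin ligase, rose in SU-DHL-1 with SD36 from 22.4 ± 0.840 to 28.4 ± 1.42, log2 fold change 0.33, SE 0.053, adjusted p = 0.00167. CRBN did not pass in MOLM-16 at 8 h (-0.10, adjusted p = 0.734) or at 24 h (-0.29, adjusted p = 0.198). STAT5A in SU-DHL-1 and STAT4 in MOLM-16 were not analysed here.

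After 8 h of SD36, more genes of MOLM-16 fell than rose, with BCL3, PIM1 and SOCS3 among the falls. BCL3 (ENSG00000069399.12, chromosome 19, 44747705 to 44760044, plus strand), a nuclear partner of NF-kB, fell from 17.5 ± 0.237 to 1.21 ± 0.188, log2 fold change -3.07, SE 0.15, adjusted p = 3.06e-05. PIM1 (ENSG00000137193.13, chromosome 6, 37170203 to 37175426, plus strand), a survival kinase, fell from 302 ± 20.5 to 74.7 ± 5.83, log2 fold change -2.00, SE 0.12, adjusted p = 7.23e-05. SOCS3 (ENSG00000184557.4, chromosome 17, 78356778 to 78360077, minus strand), the feedback inhibitor of JAK kinases, fell from 5.03 ± 0.597 to 0.545 ± 0.246, log2 fold change -1.97, SE 0.18, adjusted p = 0.000658. FOSL2, an AP-1 subunit, fell from 12.8 ± 0.181 to 3.11 ± 0.218 (-1.75, adjusted p = 0.000274), and CCND1, the cyclin of early G1, fell from 11.2 ± 0.571 to 4.53 ± 0.498 (-1.14, adjusted p = 0.00156). The largest falls also included DHRS9, a retinol dehydrogenase (-2.42, from 65.5 to 11.4), SLC6A19, an amino acid transporter (-2.29, from 23.3 to 3.98), the secreted protease ADAMTS14 (-1.88, from 39.2 to 10.0), the ligand WNT5B (-1.87, from 28.1 to 7.00) and the phosphodiesterase PDE7A (-1.75, from 92.2 to 26.8). Fewer genes rose. TCP11L2, of little known function, rose from 3.19 ± 0.166 to 8.77 ± 0.908, log2 fold change 1.22, SE 0.12, adjusted p = 0.00115, and CREBRF, a regulator of the unfolded protein response, rose from 3.42 ± 0.352 to 7.71 ± 1.10 (0.98, adjusted p = 0.00742). HIST2H4B, which has near-identical copies, rose from 1.77 ± 0.582 to 7.98 ± 0.0513 (1.71, adjusted p = 0.000658).

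At 8 h limma called 414 of 13592 genes, 139 higher and 275 lower with SD36, and 81 of them moved by at least 1 on the log2 scale. The count depended on single libraries: 155 without DMSO replicate 1, 258 without SD36 8 h replicate 1 and 175 without SD36 8 h replicate 2. In each comparison, the rule for naming the largest rises and falls took only genes with each library of 1 group above each library of the other.

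The fixed lists that fell at 8 h in MOLM-16 included STAT3 targets, stress-response and ribosome-building genes. Of 30 STAT3 targets measured, 10 fell, 0 rose and 20 did not pass, or 12 passed when adjusted over the list alone (median -0.35, adjusted p = 3.2e-11, adjusted p = 0.274 with an estimated correlation). JAK3, a cytokine-receptor kinase, was among them (-1.09, from 74.6 to 34.6). Of 31 genes of the integrated stress response, which supplies amino acids under stress, 14 fell and 0 rose (20 adjusted over the list alone; median -0.53, adjusted p = 3.85e-16, adjusted p = 0.263 with an estimated correlation). These included the transporter SLC7A5 (-1.63, from 6.19 to 1.33), the serine-synthesis enzyme PSAT1 (-1.13, from 41.6 to 18.5) and the mTOR inhibitor DDIT4 (-0.88, from 38.6 to 20.5), whose exons overlap DDIT4-AS1 over 41.2% of their bases. Of 29 nucleolar MYC targets 8 fell (20 adjusted over the list alone; median -0.40, adjusted p = 6.95e-15, adjusted p = 0.293 with an estimated correlation). MYC itself, the growth regulator, fell from 135 ± 8.71 to 79.8 ± 11.0 (-0.76, adjusted p = 0.0173; 0.0541 without DMSO replicate 2 and 0.0698 without SD36 8 h replicate 1).

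MAPK feedback genes fell at 8 h in 3 of 9 cases (8 adjusted over the list alone; median -0.58, adjusted p = 6.79e-09, adjusted p = 0.263 with an estimated correlation), with the AP-1 subunit FOSL1 at -1.05, from 4.42 to 1.63. Heat shock genes fell in 5 of 18 cases (9 adjusted over the list alone; adjusted p = 3.78e-08, adjusted p = 0.263 with an estimated correlation). Among them was the chaperone HSPA8 (-0.77, adjusted p = 0.0364; 0.113 without DMSO replicate 2, 0.134 and 0.151 without SD36 8 h replicates 1 and 2). Of 51 interferon-stimulated genes 8 fell (10 adjusted over the list alone; adjusted p = 1.01e-07, adjusted p = 0.505 with an estimated correlation). They included the DNA sensor IFI16 (-0.80, from 48.2 to 27.3) and the antiviral enzyme RSAD2 (-0.87, from 12.8 to 6.58). Of 20 interferon gamma response genes 6 fell (7 adjusted over the list alone; adjusted p = 1.1e-05, adjusted p = 0.505 with an estimated correlation). The death ligand TNFSF10 (-1.25, from 27.1 to 10.8) and the adhesion molecule ICAM1 (-0.88, from 43.4 to 23.2) were among these. Glycolysis and hypoxia genes fell in 6 of 26 cases (9 adjusted over the list alone; adjusted p = 2.29e-06, adjusted p = 0.533 with an estimated correlation). The glucose transporter SLC2A3 led them (-1.32, from 38.6 to 14.9). Replication-dependent histone genes went the other way: 4 of 59 rose (28 adjusted over the list alone; median 0.38, adjusted p = 1.95e-14, adjusted p = 0.533 with an estimated correlation). Mitosis genes shifted up slightly (0.18; 1 of 38 rose, 3 adjusted over the list alone; adjusted p = 1.85e-05, adjusted p = 0.571 with an estimated correlation). Ribosomal protein genes did so with 0 of 82 passing (0.21; adjusted p = 1.85e-05, adjusted p = 0.634 with an estimated correlation).

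After 24 h of SD36, against DMSO at 8 h, PIM1, SOCS3 and BCL3 were low in MOLM-16, and 16 of 26 glycolysis and hypoxia genes were lower. PIM1 stood at 76.7 ± 0.454 (-1.96, adjusted p = 3.05e-05), SOCS3 at 0.355 ± 0.0181 (-2.15, adjusted p = 0.000171) and BCL3 at 1.76 ± 0.502 (-2.75, adjusted p = 1.86e-05). TMEM176A and TMEM176B, neighboring genes of membrane proteins found in myeloid cells, fell from 35.4 ± 2.88 to 2.34 ± 0.243 (-3.44, adjusted p = 3.44e-06) and from 222 ± 27.7 to 21.6 ± 1.25 (-3.30, adjusted p = 3.44e-06). JAK3 fell from 74.6 ± 7.24 to 13.2 ± 0.615, log2 fold change -2.41, SE 0.13, adjusted p = 1.72e-05. VEGFA, the vessel growth factor, fell from 111 ± 16.9 to 22.6 ± 4.69, log2 fold change -2.26, SE 0.19, adjusted p = 0.000171. MUC1, a membrane mucin, fell from 21.5 ± 0.313 to 4.49 ± 1.31 (-2.06, adjusted p = 0.000122), as did the autotaxin gene ENPP2 (-2.55, from 7.58 to 0.464) and the activin antagonist FST (-2.31, from 75.1 to 14.4). TXNIP, which restrains glucose uptake, rose from 314 ± 12.1 to 973 ± 4.49, log2 fold change 1.63, SE 0.13, adjusted p = 0.000137, and its relative ARRDC4 rose from 14.2 ± 0.258 to 35.8 ± 0.0296 (1.28, adjusted p = 0.000176). FAXDC2, a gene of megakaryocytes, rose from 1.20 ± 0.129 to 6.80 ± 0.191 (1.83, adjusted p = 9.79e-05).

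The 24 h comparison called 1283 of 13592 genes, 684 higher and 599 lower. The split was 512 higher and 787 lower after rescaling by median ratios, and 471 and 772 after rescaling without small structural and mitochondrial RNAs. The count was 482 without DMSO replicate 1, 668 without SD36 24 h replicate 1 and 518 without SD36 24 h replicate 2. MOLM-16 has DMSO libraries of 8 h only, so compound and time in culture differ together here.

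Glycolysis and hypoxia genes had the lowest adjusted p of the lists at 24 h: 16 of 26 fell, 0 rose and 10 did not pass (23 adjusted over the list alone; median -0.65, adjusted p = 2.95e-18, adjusted p = 0.386 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 395 ± 1.80 to 168 ± 8.60, log2 fold change -1.23, SE 0.12, adjusted p = 0.000439. SLC2A3 (-1.65, from 38.6 to 11.6), the glycolytic regulators PFKFB3 (-1.19, from 25.8 to 10.7) and PFKFB4 (-1.30, from 20.7 to 7.82) and the mitophagy receptor BNIP3 (-1.10, from 35.7 to 16.1) also fell. Of 35 megakaryocyte and erythroid genes 16 rose and 1 fell (23 adjusted over the list alone; median 0.46, adjusted p = 2.6e-06, adjusted p = 0.526 with an estimated correlation). ALAS2, the first enzyme of heme synthesis in red cells, rose from 11.8 ± 0.560 to 26.4 ± 1.32, log2 fold change 1.10, SE 0.12, adjusted p = 0.00098. The anion exchanger SLC4A1 (1.18, from 2.10 to 6.01) and the near-identical alpha-globin genes HBA1 (1.73, from 17.2 to 59.1) and HBA2 (1.68, from 9.41 to 32.4) rose as well.

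Interferon-stimulated genes fell at 24 h in 13 of 51 cases with 0 risen (17 adjusted over the list alone; median -0.27, adjusted p = 1.35e-08, adjusted p = 0.432 with an estimated correlation). The antiviral genes MX1 (-1.13, from 95.2 to 43.0), MX2 (-1.35, from 19.8 to 7.16) and OAS2 (-1.24, from 10.6 to 3.95) were lower, and so was IFITM2 (-1.25, from 108 to 44.7), which shares 22.7% of its exonic bases with IFITM1. Stress-response genes fell in 14 of 31 cases and rose in 1 (19 adjusted over the list alone; adjusted p = 5.39e-09, adjusted p = 0.386 with an estimated correlation). DDIT4 fell to 9.41 (-1.93) and the serine-synthesis enzyme PHGDH to 11.6 (-1.17). STAT3 targets fell in 8 of 30 cases with 0 risen (15 adjusted over the list alone; median -0.26, adjusted p = 2.98e-07, adjusted p = 0.386 with an estimated correlation). MAPK feedback genes fell in 7 of 9 cases (8 adjusted over the list alone; adjusted p = 2.96e-07, adjusted p = 0.386 with an estimated correlation). CCND1 lay at -1.35 and the transcription factor ETV5 at -1.08. DNA replication and E2F target genes fell in 9 of 44 cases (18 adjusted over the list alone; median -0.27, adjusted p = 1.21e-09, adjusted p = 0.432 with an estimated correlation). The chromatin regulator UHRF1 lay at -0.83 and the replication factor MCM10 at -0.67. Nucleolar MYC targets fell in 2 of 29 cases (1 adjusted over the list alone; adjusted p = 0.000144, adjusted p = 0.527 with an estimated correlation), and MYC did not pass (-0.15, adjusted p = 0.497). Targets of p53 rose in 3 of 21 cases and fell in 0 (4 adjusted over the list alone; median 0.16, adjusted p = 0.112, adjusted p = 0.668 with an estimated correlation), and the list did not pass. Of these, the growth-arrest genes GADD45A (0.84, from 11.3 to 21.0) and BTG2 (0.80, from 9.87 to 17.9) rose.

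Tested directly, 24 h against 8 h of SD36, limma called 105 genes, 35 higher and 70 lower at 24 h. The count was 16 without SD36 8 h replicate 1 and 45 without SD36 24 h replicate 2. FAXDC2 rose between these times from 1.75 ± 0.125 to 6.80 ± 0.191, log2 fold change 1.51, SE 0.14, adjusted p = 0.00273, ARRDC4 rose from 14.9 ± 0.828 to 35.8 ± 0.0296 (1.22, adjusted p = 0.00261) and the glycophorin gene GYPE rose from 9.08 ± 0.908 to 19.1 ± 0.0234 (adjusted p = 0.00687). TMEM176A (-1.90, from 11.5 to 2.34), TMEM176B (-1.71, from 73.2 to 21.6), the kinase gene PNCK (-1.75, from 25.4 to 6.86), JAK3 (-1.32, from 34.6 to 13.2) and DDIT4 (-1.04, from 20.5 to 9.41) fell. HSPA1B, a heat shock gene with a near-identical copy in HSPA1A, rose from 6.58 ± 0.232 to 14.6 ± 0.656, log2 fold change 1.04, SE 0.11, adjusted p = 0.00663. It shares 36.5% of its exonic bases with AL671762.1. Of 44 DNA replication and E2F target genes 4 fell (31 adjusted over the list alone; median -0.39, adjusted p = 3.14e-28, adjusted p = 0.369 with an estimated correlation), and 5 of 26 glycolysis and hypoxia genes fell (16 adjusted over the list alone; adjusted p = 9.27e-18, adjusted p = 0.369 with an estimated correlation). Megakaryocyte and erythroid genes rose in 8 of 35 cases (18 adjusted over the list alone; adjusted p = 1.27e-10, adjusted p = 0.477 with an estimated correlation), heat shock genes in 3 of 18 (9 adjusted over the list alone; adjusted p = 5.59e-08, adjusted p = 0.369 with an estimated correlation). Beside these, genes of dissociation and RNA decay rose in 3 of 8 cases (4 adjusted over the list alone; median 0.38, adjusted p = 0.000177, adjusted p = 0.498 with an estimated correlation). Mitochondrial transcripts shifted down with 0 of 13 passing (0 adjusted over the list alone; median -0.44, adjusted p = 0.00121, adjusted p = 0.684 with an estimated correlation). Both lists can follow RNA quality. With fry 0 lists passed in this comparison. Histone genes fell in 3 of 59 cases (8 adjusted over the list alone; median -0.31, adjusted p = 4.92e-17, adjusted p = 0.568 with an estimated correlation).

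**Figure D1:**
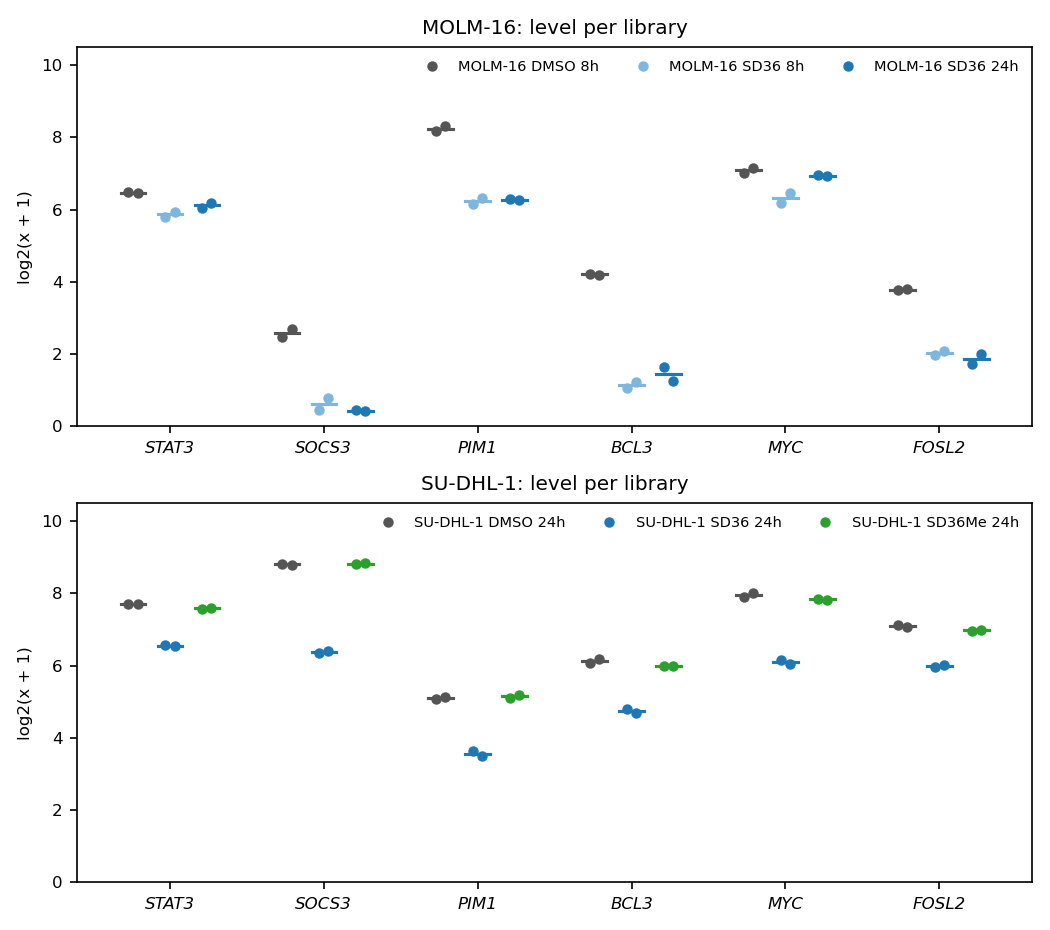
Levels of 6 genes in each library, as log2(x + 1), in MOLM-16 (top) and SU-DHL-1 (bottom); dots are libraries and bars are group means of n = 2. SOCS3 lay at a log2 fold change of -1.97 (MOLM-16, 8 h) and -2.43 (SU-DHL-1, SD36), and with SD36Me it stood at 450.0 ± 4.46 against 446 ± 6.31 with DMSO.

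In SU-DHL-1, a majority of the tested genes were called after 24 h of SD36. IL2RA, the interleukin-2 receptor alpha chain, fell from 1708 ± 84.2 to 79.1 ± 1.40, log2 fold change -4.41, SE 0.053, adjusted p = 5.04e-08. UPK1B, a tetraspanin, fell from 1627 ± 78.5 to 48.0 ± 3.57 (-5.06, adjusted p = 5.04e-08), GAS1, a membrane growth regulator, fell from 207 ± 5.88 to 8.08 ± 0.210 (-4.51, adjusted p = 5.04e-08) and the fibrinogen chain FGB fell from 77.8 ± 1.49 to 1.38 ± 0.392 (-5.06, adjusted p = 1.96e-07). The serpins SERPINB4 (-5.19, from 116 to 2.21) and SERPINB3 (-4.56, from 64.6 to 1.78), which are near-identical copies, the water and glycerol channel AQP9 (-4.15, from 205 to 10.6), the acid phosphatase ACPP (-4.33, from 63.8 to 2.23) and the pseudogene PPP1R11P1 (-4.40, from 42.9 to 1.08) fell as well. SERPINB3 shares 34.9% of its exonic bases with SERPINB11. PHLDA1, an apoptosis-linked protein, rose from 3.15 ± 0.394 to 175 ± 0.0622, log2 fold change 5.41, SE 0.071, adjusted p = 5.04e-08. S100A4, a calcium-binding protein, rose from 0.598 ± 0.179 to 73.8 ± 0.931 (5.55, adjusted p = 1.87e-07), and the keratin KRT80 rose from 0.443 to 57.5 ± 0.934 (5.34, adjusted p = 8.42e-08). SPP1, which encodes osteopontin, rose from 31.7 to 1221 ± 33.6, log2 fold change 5.22, SE 0.048, adjusted p = 5.04e-08. The lysosomal protein LAPTM5 (4.29, from 0.153 to 21.5), the lymphocyte glycoprotein CD52 (4.28, from 0.231 to 22.8) and the adaptor APBB1 (4.32, from 2.65 to 71.5) rose too.

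Limma called 8131 of 13375 genes here, 4777 higher and 3354 lower, and 1259 of them moved by at least 1 on the log2 scale. The split depended on the scaling: 3918 higher and 4154 lower after rescaling by median ratios, 3934 and 3963 after quantile normalization, but 4907 and 3321 after rescaling without small structural and mitochondrial RNAs.

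STAT3 targets of SU-DHL-1 fell in 33 of 46 cases, rose in 10 and did not pass in 3 (44 passed adjusted over the list alone; median -0.95, adjusted p = 2.79e-09, adjusted p = 0.184 with an estimated correlation). SOCS3 fell from 446 ± 6.31 to 81.8 ± 1.89, log2 fold change -2.43, SE 0.042, adjusted p = 1.08e-07. CD274, the checkpoint ligand PD-L1, fell from 52.5 ± 0.0286 to 7.03 ± 0.330 (-2.74), TNFRSF8, the CD30 receptor, fell from 130.4 ± 5.55 to 18.8 ± 1.03 (-2.73) and the costimulatory receptor ICOS fell from 63.9 ± 0.950 to 5.03 ± 0.435 (-3.43). MYC fell from 246 ± 13.8 to 67.8 ± 3.85, log2 fold change -1.85, SE 0.058, adjusted p = 9.28e-07. PIM1 (-1.54, from 33.5 to 10.9), BCL3 (-1.38, from 69.0 to 25.9), the feedback inhibitor CISH (-1.90, from 21.7 to 5.12) and the interleukin-6 receptor IL6R (-2.56, from 58.4 to 9.09) fell. Against these, the survival genes MCL1 (1.33, from 109 to 276) and BCL2L1 (1.20, from 11.5 to 27.7) rose, the latter overlapping the antisense gene ABALON over 43% of its exonic bases. Of 26 genes of an ALK lymphoma signature 18 fell and 6 rose (24 adjusted over the list alone; adjusted p = 1.88e-06, adjusted p = 0.336 with an estimated correlation). Without the genes that this signature shares with other lists it did not pass (adjusted p = 0.337).

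Genes of cell division fell nearly as a whole with SD36. Of 44 DNA replication and E2F target genes 43 fell and 0 rose (43 adjusted over the list alone; median -1.25, adjusted p = 7.05e-22, adjusted p = 0.371 with an estimated correlation). MCM2, a subunit of the replicative helicase, fell from 98.0 ± 3.85 to 22.6 ± 0.832, log2 fold change -2.07, SE 0.048, adjusted p = 2.77e-07, and its partners MCM3, MCM4 and MCM5 fell too, with log2 fold changes of -1.59, -1.61 and -1.66. Of 38 mitosis genes 37 fell (37 adjusted over the list alone; median -0.55, adjusted p = 1.32e-14, adjusted p = 0.342 with an estimated correlation). The mitotic kinase AURKB (-1.32, from 49.1 to 19.1), the kinesin KIF2C (-1.09, from 43.0 to 19.7) and cyclin CCNA2 (-1.02, from 46.2 to 22.3) were among them. Histone genes fell in 53 of 59 cases and rose in 2 (55 adjusted over the list alone; median -0.95, adjusted p = 4.06e-15, adjusted p = 0.541 with an estimated correlation). Linker histone HIST1H1B lay at -1.39, from 687 to 262. Nucleolar MYC targets fell in 27 of 29 cases (28 adjusted over the list alone; median -0.67, adjusted p = 1.07e-12, adjusted p = 0.336 with an estimated correlation). The polyamine enzyme ODC1 (from 433 to 152) and the nucleolar protein NOLC1 (-1.30, from 115 to 46.1) fell with them. Heat shock genes fell in 11 of 19 cases and rose in 2 (14 adjusted over the list alone; adjusted p = 0.00797, adjusted p = 0.521 with an estimated correlation). The HSP90 cofactor AHSA1 fell (-1.05, from 146 to 70.1) and HSPA8 rose (0.65, from 405 to 636).

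MAPK feedback genes rose in 10 of 12 cases and fell in 1 (11 adjusted over the list alone; median 0.67, adjusted p = 0.00115, adjusted p = 0.385 with an estimated correlation). SPRY4, an inhibitor of receptor signaling, rose from 6.54 ± 0.263 to 115 ± 3.75, log2 fold change 3.95, SE 0.058, adjusted p = 6.73e-08, and the ERK phosphatase DUSP6 rose from 57.1 ± 0.551 to 198 ± 3.52 (1.77, adjusted p = 2.36e-07), although 40.5% of its exonic bases lie in another gene. Targets of p53 rose in 17 of 24 cases and fell in 2 (21 adjusted over the list alone; median 0.46, adjusted p = 0.00544, adjusted p = 0.607 with an estimated correlation). They included the oxidoreductase TP53I3 (1.59, from 8.41 to 27.3), PHLDA3, an AKT inhibitor (1.30), and the death receptor FAS (0.98, from 8.77 to 18.3), while GADD45A fell from 219 ± 3.96 to 46.8 ± 2.32 (-2.20).

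Immune genes of SU-DHL-1 moved both ways, and none of these lists passed with camera, which compares a list with all other genes. All 6 passed with fry, which tests a list by itself (adjusted p = 0.000131 to 0.022). In this comparison 60.8% of the tested genes were called and 28 lists passed with fry, so passing it does not set these lists apart from other genes. Of 42 interferon-stimulated genes 24 rose and 11 fell (35 adjusted over the list alone; adjusted p = 0.114, adjusted p = 0.677 with an estimated correlation). OASL, an antiviral protein, rose from 7.41 ± 0.877 to 54.2 ± 2.33 (2.72) and the scramblase PLSCR1 fell from 318 ± 0.590 to 125 ± 3.44 (-1.34). Of 20 antigen presentation genes 11 rose and 5 fell (16 adjusted over the list alone; adjusted p = 0.249, adjusted p = 0.677 with an estimated correlation). The class II genes HLA-DRA (3.92, from 0.232 to 17.7) and CD74 (3.66, from 0.309 to 15.5) rose from under 1, and NLRC5, a regulator of class I genes, rose to 9.74 (1.61). Of 12 T and NK cell genes 4 rose and 7 fell (11 adjusted over the list alone; median -0.40, adjusted p = 0.242, adjusted p = 0.617 with an estimated correlation). The protease GZMA rose from 238 ± 1.36 to 2111 ± 88.9 (3.14) and the T-cell factor LEF1 fell from 44.9 ± 2.56 to 6.99 ± 0.127 (-2.52). Cytokine and receptor genes rose in 13 and fell in 16 of 31 cases (29 adjusted over the list alone; adjusted p = 0.114, adjusted p = 0.484 with an estimated correlation), with the interleukin-1 coreceptor IL1RAP lower (-2.92, from 678 to 88.8). For 18 NF-kB targets, 8 rose and 7 fell (15 adjusted over the list alone; median -0.0054, mean 0.19, test direction down, adjusted p = 0.81, adjusted p = 0.853 with an estimated correlation). The cytokine TNF (3.21, from 0.979 to 17.1) rose and the inhibitor NFKBIA (-2.22, from 105 to 21.7) fell. Of 12 checkpoint and costimulation genes 3 rose and 6 fell (9 adjusted over the list alone; adjusted p = 0.078, adjusted p = 0.607 with an estimated correlation). TNFRSF9, a costimulatory receptor, fell from 49.2 ± 0.355 to 9.52 ± 0.522 (-2.26). Apart from these, BCL2 family genes, regulators of cell death, rose in 10 and fell in 2 of 14 cases (12 adjusted over the list alone; adjusted p = 0.0746, adjusted p = 0.484 with an estimated correlation; adjusted p = 0.000507 with fry). The survival gene BCL2A1 was lower (-0.74, from 239.5 to 143).

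**Figure D2:**
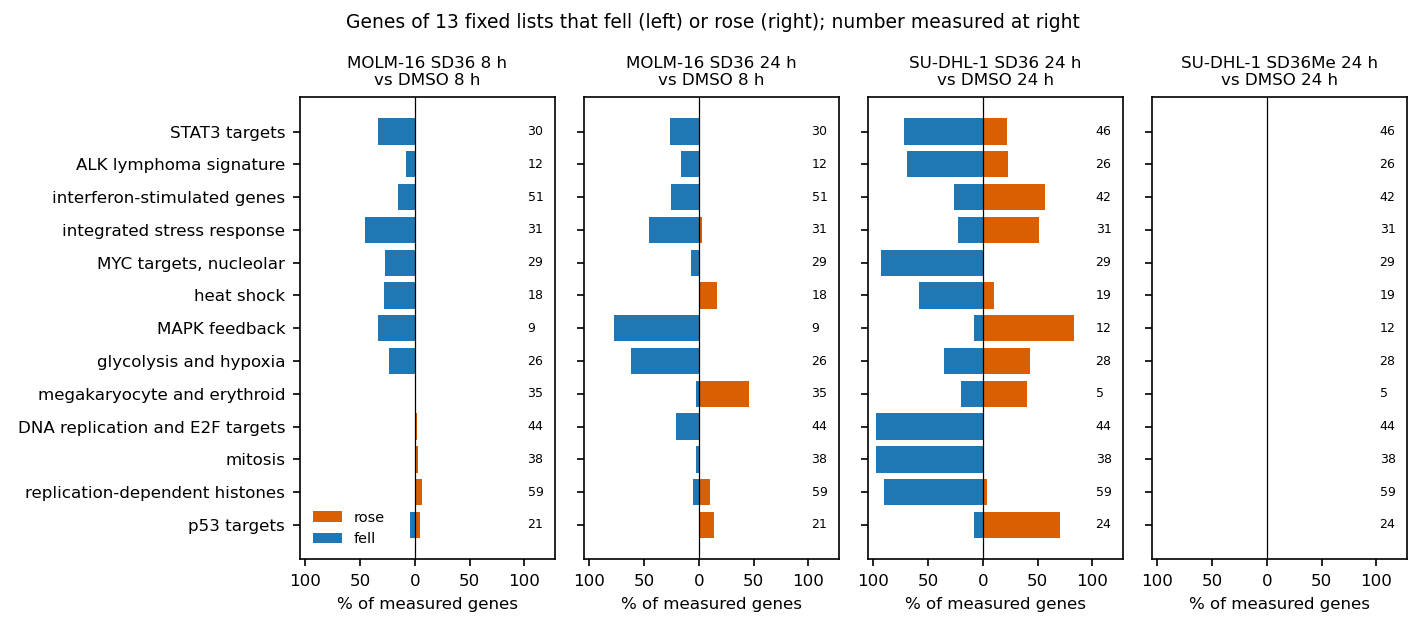
Percent of measured genes of 13 fixed lists that rose (right) or fell (left) in 4 comparisons, with the number measured beside each bar. DNA replication genes fell in 43 of 44 cases with SD36 in SU-DHL-1, glycolysis and hypoxia genes in 16 of 26 cases in MOLM-16 at 24 h, and the SD36Me panel has 0 called genes.

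SD36Me left the genes that SD36 moved most near their DMSO levels in SU-DHL-1. IL2RA stood at 1660.3 ± 9.98 with SD36Me against 1708 ± 84.2 with DMSO (log2 fold change -0.040, 95% CI -0.17 to 0.086), SOCS3 at 450.0 ± 4.46 (0.014, 95% CI -0.086 to 0.11) and UPK1B at 1676 ± 30.7 (0.044, 95% CI -0.11 to 0.20). Limma called 0 of 13375 genes, with 1957 at an unadjusted p under 0.05 where 668.8 were expected by chance, and the lowest adjusted p was 0.117. Without SD36Me replicate 1 the count was 3. The 95% CI lay within 1 of 0 on the log2 scale for 97.7% of genes and within 0.5 for 87%. Among STAT3 targets the protease FURIN (-0.25, 95% CI -0.37 to -0.14), TNFRSF8 (-0.28, 95% CI -0.41 to -0.15) and CISH (-0.25, 95% CI -0.46 to -0.042) lay below DMSO without passing (adjusted p = 0.201, 0.201 and 0.294). SPP1, which rose with SD36, lay at -0.29 (adjusted p = 0.179).

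Small shifts of whole lists passed with SD36Me at the preset correlation, all with 0 genes called. With fry only 1 of these lists passed. Myeloid maturation genes had a median of -0.21 over 7 genes (adjusted p = 0.00044, adjusted p = 0.518 with an estimated correlation), T and NK cell genes one of -0.15 over 12 (adjusted p = 0.00135, adjusted p = 0.562 with an estimated correlation), the granule protein gene NKG7 lying at -0.27 and the receptor CD5 at -0.31. STAT3 targets had a median of -0.040 over 46 (adjusted p = 0.00576, adjusted p = 0.518 with an estimated correlation), which ended without DMSO replicate 2 (adjusted p = 0.119). The mitosis list had a median of 0.085 (adjusted p = 0.00135, adjusted p = 0.619 with an estimated correlation), which ended without DMSO replicate 1 (0.116). The histone list had a median of 0.11 (adjusted p = 0.00135, adjusted p = 0.76 with an estimated correlation), which ended without DMSO replicate 1 (0.711) or SD36Me replicate 1 (0.488). In all, 9 lists passed, and 4 did so without DMSO replicate 1 or without SD36Me replicate 1.

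Tested directly against each other, SD36 and SD36Me differed at STAT3, which stood at 92.7 ± 0.941 with SD36 and 191 ± 4.30 with SD36Me (log2 difference, SD36 minus SD36Me, -1.03, 95% CI -1.13 to -0.94, adjusted p = 2e-06). Lower with SD36 were SOCS3 (-2.45, 95% CI -2.55 to -2.35), IL2RA (-4.37, 95% CI -4.50 to -4.25), MYC (-1.73, 95% CI -1.87 to -1.59) and the signaling regulator RGS16 (-3.94, 95% CI -4.07 to -3.81). Higher with SD36 were SPP1 (5.51, 95% CI 5.40 to 5.63), the hepatic lectin gene ASGR2 (4.47, 95% CI 4.27 to 4.67) and the DNA deaminase APOBEC3H (4.28, 95% CI 4.08 to 4.49). TRAC, the T-cell receptor alpha constant gene, was higher with SD36 (3.27, from 0.276 to 11.3), as were GZMA (3.36, from 205 to 2111) and HLA-DRA (3.98, from 0.182 to 17.7). The test called 7801 genes, 4419 higher and 3382 lower with SD36, 1237 of them by at least 1 on the log2 scale. The split was 3862 and 4039 after rescaling by median ratios.

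The lists were compared between the compounds as well. Of 46 STAT3 targets 33 were lower and 10 higher with SD36 (43 adjusted over the list alone; adjusted p = 1.17e-08, adjusted p = 0.204 with an estimated correlation). DNA replication genes were lower in 43 of 44 cases (44 adjusted over the list alone; adjusted p = 2.31e-21, adjusted p = 0.344 with an estimated correlation), with the polymerase subunit POLE2 at -1.61. Mitosis genes were lower in 38 of 38 cases (38 adjusted over the list alone; adjusted p = 1.48e-15, adjusted p = 0.315 with an estimated correlation) and histone genes in 55 of 59, with 2 higher (57 adjusted over the list alone; adjusted p = 1.46e-16, adjusted p = 0.565 with an estimated correlation). Nucleolar MYC targets were lower in 26 of 29 cases (26 adjusted over the list alone; adjusted p = 5.74e-12, adjusted p = 0.315 with an estimated correlation). MAPK feedback genes were higher in 10 and lower in 1 of 12 cases (11 adjusted over the list alone; adjusted p = 0.000558, adjusted p = 0.344 with an estimated correlation), and p53 targets in 19 and 2 of 24 cases (21 adjusted over the list alone; adjusted p = 0.00228, adjusted p = 0.596 with an estimated correlation).

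**Figure D3:**
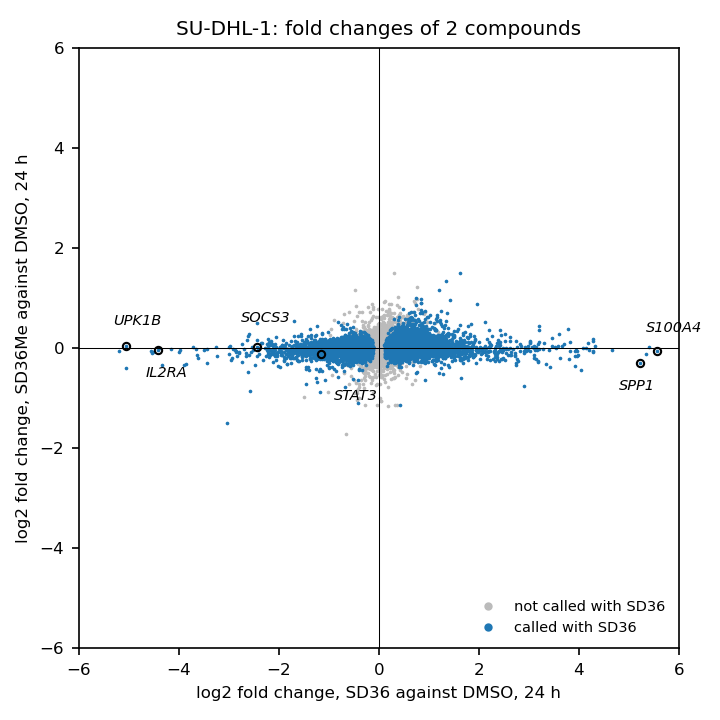
Log2 fold change against DMSO at 24 h in SU-DHL-1 for each tested gene, SD36 on the horizontal axis and SD36Me on the vertical axis; genes called with SD36 are colored. S100A4 lay at 5.55 with SD36 and -0.055 with SD36Me, UPK1B at -5.06 and 0.044.

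Effects that share DMSO libraries correlate by construction, so each correlation and covariance is given beside its value in 100 simulations of unchanged groups against the same controls. In MOLM-16 the fold changes of 8 h and 24 h correlated at 0.719 across 13592 genes (0.501 simulated), with a covariance of 0.0727 (0.0125 simulated). Both times called 109 genes higher, where 6.99 would overlap by chance, and 196 lower (12.1 by chance). These chance values take no account of the shared controls. The simulations gave 0.08 and 0.05 such genes on average. As they held no changed genes, they cannot show how far shared controls raise the overlap of real calls or the correlation of real effects. Among the genes lower at both times were BCL3, PIM1 and SOCS3. In opposite directions 0 genes were higher and then lower (6.13 by chance) and 1 was lower and then higher (13.8 by chance): HSPA1B, singled out after its values were seen, at -0.49 and 0.55. Its 8 h call ended without any 1 of the 6 libraries: adjusted p = 0.153 and 0.148 without DMSO replicates 1 and 2, 0.0903 and 0.0861 without SD36 8 h replicates 1 and 2, 0.0796 and 0.0819 without SD36 24 h replicates 1 and 2. Its 24 h call ended without DMSO replicate 1 (0.0938) and without SD36 24 h replicates 1 and 2 (0.0654 and 0.139). With a different control library for each time, the correlation was 0.515 or 0.435, values that rest on 1 DMSO library per effect and have no test.

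In SU-DHL-1 the fold changes of SD36 and SD36Me correlated at 0.142 across 13375 genes (0.5 simulated), with a covariance of 0.0157 (0.00591 simulated). The observed and simulated correlations cannot be compared. The SD36 fold changes had a variance of 0.455 against 0.0269 for SD36Me, while both simulated groups were unchanged. The slope of SD36Me on SD36 was 0.0345. With a different control library for each compound the correlation was 0.0474 or 0.0419, again with no test. No gene was called with both, since 0 were called with SD36Me, against 0 expected per direction. Part of each covariance above its simulated value may still come from the shared controls, since the simulations used a spread pooled over the groups of a line. With different control libraries the covariance was 0.0598 or 0.0515 between the times in MOLM-16. Between the compounds in SU-DHL-1 it was 0.00636 or 0.00532. Genes are not independent replicates, so these correlations carry no p-value.

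Some genes moved the same way in both lines with SD36, and others moved apart. The MOLM-16 values here are of 24 h against DMSO at 8 h, so in that line time in culture differs along with the compound. PIM1 fell in MOLM-16 at 24 h (-1.96) and in SU-DHL-1 (-1.54), and so did SOCS3 (-2.15 and -2.43), BCL3 (-2.75 and -1.38), FOSL2 (-1.91 and -1.12) and LEF1 (-0.82 and -2.52). TXNIP rose in both (1.63 and 2.37), as did BTG2 (0.80 and 0.76) and TCP11L2 (from 3.19 to 7.37 and from 4.12 to 8.16). SPP1 fell in MOLM-16 (-2.17) and rose in SU-DHL-1 (5.22), as did VEGFA (-2.26 and 0.83), DDIT4 (-1.93 and 1.56), PFKFB4 (-1.30 and 2.63) and OASL (-1.21 and 2.72). GADD45A went the opposite way (0.84 and -2.20). Whether the lines differ was not tested.

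Across 11321 genes tested in both lines, the SU-DHL-1 fold changes correlated at 0.13 with those of MOLM-16 at 8 h and at 0.139 with those at 24 h. At 24 h both lines called 295 genes higher (193 by chance) and 162 lower (92.5 by chance), PIM1 and SOCS3 among the latter. Opposite calls numbered 60 higher in MOLM-16 and lower in SU-DHL-1 (136 by chance), such as GADD45A, and 111 the other way (132 by chance), such as SPP1. With the 8 h effects of MOLM-16 the counts were 58 higher in both (38 by chance) and 101 lower in both (45.6 by chance), BCL3 and FOSL2 among these, and 10 and 40 opposite (26.6 and 65.1 by chance).

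**Figure D4:**
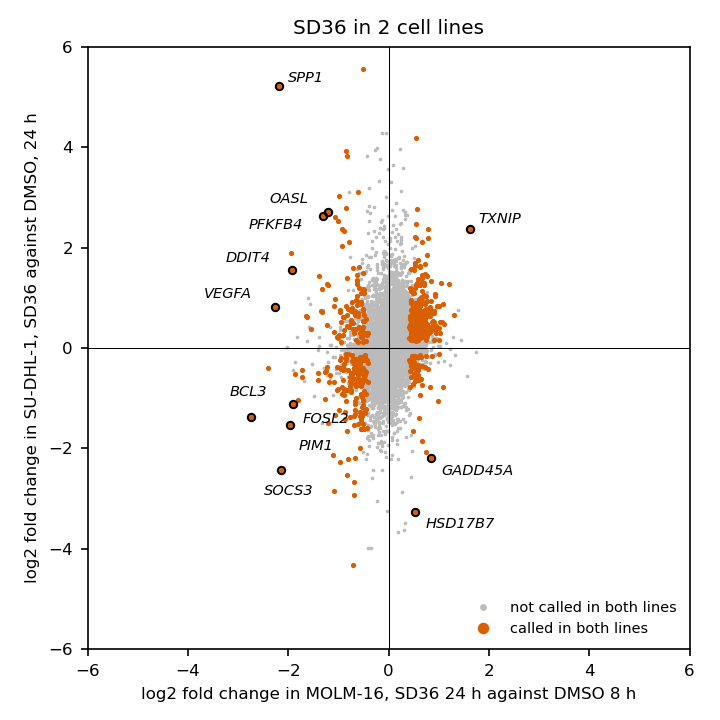
Log2 fold change with SD36 in MOLM-16 (24 h against DMSO at 8 h, horizontal axis) and in SU-DHL-1 (24 h against DMSO at 24 h, vertical axis) for each gene tested in both; genes called in both lines are colored. TXNIP lay at 1.63 and 2.37, BCL3 at -2.75 and -1.38, SPP1 at -2.17 and 5.22.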

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

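Of the tests in this part, those on the glycolysis and hypoxia genes (their shift at 8 h, and rescaling by median ratios) were chosen only after the result was seen, while the comparison of 24 h with 8 h was planned. Groups of 2 libraries are too small for a search for outlying libraries.

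With SD36, MOLM-16 differed between 24 h and 8 h at 105 genes, by a direct limma test of these times. With 0 DMSO libraries at 24 h, this test does not separate the compound from time in culture. The count was 16 without SD36 8 h replicate 1, 45 without SD36 24 h replicate 2, 54 with a replicate block, 57 without the variance trend and 231 with a mean of at least 5. Red cell and platelet lineage genes were higher at 24 h: FAXDC2 by 1.51 on the log2 scale, HBA1 by 1.31, HBA2 by 1.34 and SLC4A1 by 1.20, and GYPE (from 9.08 to 19.1) rose with them. Also higher were ARRDC4 at 1.22, TXNIP at 1.02 and the heat shock genes HSPA1B at 1.04, HSPA1A at 0.90 and the cochaperone DNAJB1 at 0.61, as were the interferon-induced genes IRF1 (0.88) and WARS (0.77), the ribosome-building gene RRS1 (0.73), the kinase PIM2 (0.85) and the small nucleolar RNA SNORD14D (1.16), which lies within HSPA8. Lower at 24 h were TMEM176A (-1.90), TMEM176B (-1.71), PNCK (-1.75), JAK3 (-1.32), VEGFA (-1.32), the growth-factor binding protein IGFBP7 (-1.15), the liver protein gene OIT3 (-1.10) and DDIT4 (-1.04). The snoRNAs SNORD117 (-1.52) and SNORD95 (-1.27, within RACK1) were lower too. So were the replication genes MCM10 (-0.77), CCNE2 (-0.85), E2F1 (-0.80) and UHRF1 (-0.76), the histones HIST1H1D (-0.77) and HIST1H2BM (-0.76), and the hypoxia genes ANKRD37 (-0.94), ALDOC (-0.97) and BNIP3 (-0.77). CCNE2 shares 37% of its exonic bases with INTS8, and ANKRD37 shares 35.2% with UFSP2. Under some setting other than leaving out a library, calls ended for HBA2, SNORD14D, SNORD117, VEGFA, SNORD95, CCNE2 and UHRF1. The same held for IRF1, HIST1H2BM, RRS1, DNAJB1, ANKRD37 and BNIP3.

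For FAXDC2, ARRDC4, HSPA1B, GYPE, TMEM176A, TMEM176B, PNCK, JAK3, OIT3 and DDIT4 the call held whichever library was left out. Without SD36 8 h replicate 1 the calls of all the other genes of the previous paragraph ended, at adjusted p from 0.0561 (SLC4A1, IGFBP7 and UHRF1) to 0.177 (SNORD95). Without SD36 8 h replicate 2 calls ended for SNORD14D, TXNIP, SNORD117, VEGFA, SNORD95, E2F1, UHRF1, WARS, HIST1H1D, HIST1H2BM, DNAJB1 and ALDOC (0.06 for TXNIP to 0.107 for SNORD14D). Without SD36 24 h replicate 1 they ended for SNORD14D, MCM10, E2F1, UHRF1, IRF1, WARS, HIST1H1D, HIST1H2BM, RRS1, DNAJB1 and BNIP3 (0.0615 for HIST1H2BM to 0.154 for DNAJB1). Without SD36 24 h replicate 2 they ended for SNORD95, MCM10, CCNE2, E2F1, UHRF1, WARS, HIST1H1D, HIST1H2BM, RRS1, DNAJB1, ANKRD37, BNIP3 and PIM2 (0.052 for ANKRD37 to 0.215 for RRS1).

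By lists, 24 h minus 8 h of SD36 gave medians of -0.39 for DNA replication and E2F targets, -0.26 for mitosis, -0.46 for glycolysis and hypoxia, -0.31 for histones, -0.37 for T and NK cell genes, -0.44 for mitochondrial transcripts and -0.05 for interferon-stimulated genes. They were 0.39 for megakaryocyte and erythroid genes, 0.31 for heat shock, 0.24 for nucleolar MYC targets, 0.38 for dissociation and RNA decay genes, 0.21 for AP-1 genes, 0.21 for the STAT family, 0.15 for antigen presentation and 0.13 for the interferon gamma response. These 15 lists passed at the preset correlation. With an estimated correlation 0 passed (adjusted p = 0.369 to 0.684), and with fry 0 passed. Without SD36 8 h replicate 1 the STAT family (0.208), interferon-stimulated genes (0.184), antigen presentation (0.184) and AP-1 genes (0.215) no longer passed. Without SD36 8 h replicate 2 the interferon gamma response (0.161) and mitochondrial transcripts (0.0647) did not. Without SD36 24 h replicate 1 the STAT family (0.0559), interferon-stimulated genes (0.137) and AP-1 genes (0.0618) did not, and without SD36 24 h replicate 2 the STAT family (0.0935), antigen presentation (0.158) and mitochondrial transcripts (0.945) did not.

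Several genes moved one way in both SD36 libraries of MOLM-16 at the time named and the opposite way in both SD36 libraries of SU-DHL-1; the difference between the cell lines was not tested. With MOLM-16 at 8 h given first, then SU-DHL-1, lower and then higher were C10orf10 (-1.77 and 1.90), SLC7A5 (-1.63 and 0.72), DDIT4 (-0.88 and 1.56), VEGFA (-0.94 and 0.83), HSPA8 (-0.77 and 0.65), MX2 (-0.71 and 0.75) and SPP1 (-1.32 and 5.22). The MOLM-16 calls of VEGFA ended without DMSO replicate 2 (0.086) or SD36 8 h replicate 1 (0.111), those of MX2 without DMSO replicate 2 (0.0562) or SD36 8 h replicate 2 (0.0534), and those of HSPA8 without DMSO replicate 2 (0.113), SD36 8 h replicate 1 (0.134) or replicate 2 (0.151). HIST1H2AC (0.74 and -0.78) went the other way; its call ended without DMSO replicate 1 (0.0872), SD36 8 h replicate 1 (0.0547) or replicate 2 (0.0861). STAT2 (0.31 and -0.11) was called in neither line (adjusted p = 0.219 and 0.0905), and STAT5B (0.12 and -0.51) only in SU-DHL-1.

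With MOLM-16 at 24 h against DMSO at 8 h, lower and then higher were C10orf10 (-1.95 and 1.90), DDIT4 (-1.93 and 1.56), MX2 (-1.35 and 0.75), VEGFA (-2.26 and 0.83), SPP1 (-2.17 and 5.22), PFKFB4 (-1.30 and 2.63), BNIP3 (-1.10 and 0.83) and OASL (-1.21 and 2.72). CRBN (-0.29 and 0.33) was not called in MOLM-16. Higher and then lower were HIST1H2AC (0.83 and -0.78), GADD45A (0.84 and -2.20) and HSD17B7 (0.53 and -3.26), the last a MOLM-16 call that ended without DMSO replicates 1 or 2 (0.17 and 0.0664) or SD36 24 h replicates 1 or 2 (0.162 and 0.127). STAT5B (0.21 and -0.51) had no call in MOLM-16. STAT2 (0.48 and -0.11) was called there but not in SU-DHL-1 (adjusted p = 0.0905), and its call ended without DMSO replicates 1 or 2 (0.189 and 0.0667) or either SD36 24 h replicate (0.175).

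Glycolysis and hypoxia genes were lower in MOLM-16 at 24 h of SD36 than in DMSO at 8 h, and time in culture is a possible explanation because the MOLM-16 DMSO libraries are all of 8 h. The list passed at the preset correlation but not with an estimated correlation at 24 h (adjusted p = 0.386), at 8 h (0.533) or from 8 h to 24 h (0.369). Time alone, as the whole cause, is argued against by the 8 h groups, which had equal time. There the list's median lay -0.272 from that of all genes (SD 0.00672 over leaving out each library of the line). The SD36 24 h libraries do not enter this value, so that SD understates its spread. Rescaling by median ratios cannot decide on the scaling of the libraries. It moves all genes of a library about alike, and the median of all genes at 24 h was only 0.06. After that step the list's median at 24 h was -0.72 (SD 0.0404 over leaving out each library of the line). The SD36 8 h libraries do not enter this median, so its SD is understated too. The list thus lay below the median of all genes under either scaling. The further fall from 8 h to 24 h, with a median of -0.462, cannot be told apart from an effect of time, because there were 0 DMSO libraries at 24 h. A further action of SD36 stays open beside it.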

How the results depend on the processing

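Quantile normalization, rescaling by median ratios, rescaling without small structural and mitochondrial RNAs, limma without trend, and quantile normalization and leaving out libraries for the agreements were chosen after the data were seen; the other alternatives were planned. Leaving out a library leaves a group with 1, which is assumed to vary like the other groups. Alternatives that need counts (normalization factors, filters on counts and tests for counts) were not run, because the values are not counts. No called gene or list named here reversed, while lists not called could change sign between scalings. The balance of higher and lower calls did turn with the scaling: after rescaling by median ratios from 684 and 599 to 512 and 787 (MOLM-16, 24 h), from 4777 and 3354 to 3918 and 4154 (SD36) and from 4419 and 3382 to 3862 and 4039 (SD36 against SD36Me). At 24 h in MOLM-16 it also turned with a fold minimum of 1 on the log2 scale (48 and 142), after quantile normalization (624 and 723), after rescaling without small structural and mitochondrial RNAs (471 and 772), without DMSO replicate 1 (162 and 320) or 2 (570 and 591), without SD36 24 h replicate 1 (275 and 393) or 2 (191 and 327), and without trend (577 and 584). In SU-DHL-1 it also turned after quantile normalization (3934 and 3963 with SD36, 3852 and 3961 for SD36 against SD36Me). For 24 h against 8 h it turned from 35 and 70 to 43 and 33 without SD36 8 h replicate 2 and to 23 and 22 without SD36 24 h replicate 2. A fold minimum of 1 on the log2 scale left 81 (MOLM-16, 8 h), 190 (24 h) and 28 (24 h against 8 h) genes, and 1259 (SD36), 0 (SD36Me) and 1237 (SD36 against SD36Me) in SU-DHL-1; the criterion itself is stricter. The 105 genes of 24 h against 8 h became 231 with a mean of at least 5, where fewer genes were tested, 54 with a replicate block and 57 without trend; the cause was not tested for the latter pair. The block crossed no other count by 1.5 times (403, 1508, 7863, 0 and 7575 genes), and replicates share only a number: their differences correlated at 0.13, 0.14 and -0.095 between MOLM-16 groups and at -0.068, -0.047 and -0.00075 between SU-DHL-1 groups.

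With an estimated correlation, which allows for genes of a list moving together, 0 lists passed in each of the 6 comparisons. The cause was not tested. That version was not run on the simulated data, so whether it can call a shifted list here is not known. It had only 3 residual degrees of freedom per fit, so its lack of calls is no evidence that the lists were unshifted. With fry 6 (MOLM-16, 8 h), 10 (24 h), 0 (24 h against 8 h), 28 (SD36), 1 (SD36Me) and 29 (SD36 against SD36Me) lists passed; the cause was not tested. With separate control libraries the agreement was 0.515 or 0.435 between the times in MOLM-16 and 0.047 or 0.042 between the compounds, each on 1 control library per effect. Among genes called in either line the agreement between lines was 0.154 (8 h) and 0.157 (24 h), against 0.13 and 0.139 over all genes; fewer genes enter it.

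Leaving out 1 library gave 155 (without DMSO replicate 1) to 405 genes at 8 h in MOLM-16, 482 (without DMSO replicate 1) to 1809 (without SD36 8 h replicate 1) at 24 h, and 16 (without SD36 8 h replicate 1) to 144 for 24 h against 8 h. Other counts that moved by over 1.5 times were 258 and 175 at 8 h (without SD36 8 h replicates 1 and 2), 668 and 518 at 24 h (without SD36 24 h replicates 1 and 2) and 45 for 24 h against 8 h (without SD36 24 h replicate 2). In SU-DHL-1 it gave 6638 to 7932 (SD36), 0 to 3 (SD36Me, 3 without its replicate 1) and 6423 to 7973 (SD36 against SD36Me). Lists that passed numbered 12 to 18, 11 to 14 and 11 to 15 in the MOLM-16 comparisons, and 9 to 12, 4 to 10 (4 without DMSO replicate 1 or SD36Me replicate 1) and 10 to 12 in those of SU-DHL-1. The agreement was 0.589 to 0.791 between times, 0.121 to 0.210 between compounds, and 0.096 to 0.145 (8 h) and 0.107 to 0.156 (24 h) between lines.

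Of 365 results of named genes 318 were called. Of these, 34 were lost under some setting other than leaving out a library, 76 when some library was left out, 242 under neither, and 0 turned. Counted over settings, named genes stayed called or uncalled as before in 1967 cases of leaving out a library (218 weaker, 5 stronger) and in 3460 other cases (171 weaker, 13 stronger). Lists did so in 1200 (48 weaker, 27 stronger) and in 2317 (143 weaker, 67 stronger). With 2 libraries per group, changes of 0.5 on the log2 scale were recovered in 25.4% of simulated cases in MOLM-16 and 70.1% in SU-DHL-1. The simulations also called 17 unchanged genes in MOLM-16 and 24 in SU-DHL-1. That is a larger share of the simulated calls than the threshold on adjusted p is meant to allow.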

Other observations

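Of the tests in this part, those of rescaling by median ratios, of length and level for the balance of rises and falls, and of RNA from MOLM-16 cells were chosen only after the result was seen. Those of length and level for the number of calls and of overlapping genes were written before.

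With SD36, SU-DHL-1 changed genes of redox balance and lipid synthesis in both directions. Of 18 NRF2 targets 7 rose and 7 fell (15 adjusted over the list alone; adjusted p = 0.987, adjusted p = 0.987 with an estimated correlation), and the list's median of 0.011 turned negative after rescaling by median ratios or without small structural and mitochondrial RNAs. NQO1, a quinone reductase, rose from 11.0 ± 0.608 to 54.7 ± 2.04 (2.22), the autophagy receptor SQSTM1 rose from 22.0 ± 0.0564 to 104 ± 1.39 (2.19), the peroxidase PRDX1 rose to 445 (1.31) and thioredoxin TXN fell to 339 (-0.82). The cystine transporter SLC7A11 rose from 2.35 ± 0.147 to 7.39 ± 0.193 (1.33). Of 23 cholesterol synthesis genes 14 rose and 4 fell (19 adjusted over the list alone; adjusted p = 0.21, adjusted p = 0.741 with an estimated correlation). Lanosterol synthase LSS rose from 3.22 ± 0.204 to 12.5 ± 0.380 (1.68), while HSD17B7, a late enzyme of the pathway, fell from 178 ± 6.36 to 17.7 ± 0.577 (-3.26, adjusted p = 7.21e-08). Of 28 glycolysis and hypoxia genes of SU-DHL-1 12 rose and 10 fell (24 adjusted over the list alone; adjusted p = 0.81, adjusted p = 0.935 with an estimated correlation), with the glucose transporter SLC2A1 raised from 26.4 to 76.5 and pyruvate kinase PKM at 1.04, from 523 to 1077.

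Cereblon and its neosubstrates, the proteins that cereblon-binding compounds can degrade, showed 5 rises and 2 falls of 14 measured RNAs in SU-DHL-1 (6 adjusted over the list alone; adjusted p = 0.697, adjusted p = 0.741 with an estimated correlation). The ligase subunit DDB1 (-0.32, from 86.7 to 69.4) and the translation factor GSPT1 (-0.33, from 92.7 to 73.5) fell, and RNF166 rose (0.65, from 11.4 to 18.4). Endoplasmic reticulum chaperone genes rose in 4 and fell in 7 of 21 cases (11 adjusted over the list alone; median -0.062, mean 0.0192, adjusted p = 0.282, adjusted p = 0.741 with an estimated correlation), with the degradation factor EDEM1 higher (1.21, from 34.8 to 81.6). In MOLM-16 the chaperone HSPA5 fell at 8 h (-1.05, from 37.6 to 17.5). Nuclear genes of oxidative phosphorylation rose in 18 and fell in 2 of 32 cases (20 adjusted over the list alone; adjusted p = 0.078, adjusted p = 0.741 with an estimated correlation), with UQCRC1 of complex III at 0.60, from 106 to 162 and ATP5G1 of the ATP synthase at -0.56, from 292 to 198. That list passed as higher after quantile normalization (adjusted p = 0.000591) and without DMSO replicate 1 (0.0369) or SD36 replicate 1 (0.0342). JAK-STAT feedback genes rose in 8 and fell in 6 of 19 cases (15 adjusted over the list alone; median 0.14, mean -0.211, adjusted p = 0.732, adjusted p = 0.853 with an estimated correlation), the phosphatase PTPRC rising (0.86, from 37.0 to 68.2) and PTPN2 falling (-0.91, from 111 to 58.4). The scavenger receptor CD163 fell from 115 ± 9.71 to 17.4 ± 1.16 (-2.65) and the pseudokinase TRIB2 rose from 9.18 ± 0.269 to 64.6 ± 1.07 (2.69).

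SD36 called 60.8% of the tested genes of SU-DHL-1, more of them higher than lower. Rescaling by median ratios left 8072 calls, so the majority was seen under either scaling. That step cannot decide on the scaling of the libraries as its cause. It moves all genes of a library about alike, and by little beside the median absolute fold change of 0.303. A trend of fold change with gene length or level is argued against as the cause. Over the genes with a length, fitted separately, 7940 were called with such trends removed and 8145 before. Of these, 7034 were called in the same direction both times. As for why more genes rose than fell, the scaling, a trend of fold change with gene length or level, and a true excess of rises cannot be told apart. Of the calls 48.5% were higher after rescaling by median ratios, but that step by itself centers the fold changes (median 0.0893 before and 0.00722 after). Removing the trends left 50.9% higher, but centers the fold changes too, while fold change and mean level correlated at -0.209 (Spearman) across genes. After rescaling without small structural and mitochondrial RNAs 59.6% were higher. A wide response to SD36 stays open as an untested biological explanation.

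In SU-DHL-1 79 genes stood below 1 with DMSO and rose above 5 with SD36, by a median of 7.97, among them S100A4, KRT80, LAPTM5, CD52, HLA-DRA and CD74. RNA from MOLM-16 cells in these libraries is a candidate source, but 16 of the 24 such genes in the MOLM-16 table stood higher with SD36 than in any MOLM-16 group. That argues against this source for those 16, since a mixture cannot exceed its source. The 62 genes abundant in MOLM-16 and low in SU-DHL-1, taken without the 79, rose by a median of 2.08% of their MOLM-16 level. The median was 151% for those 24. As the 24 were selected for their rise and the 62 exclude such genes, this contrast cannot decide on that source. Reads from an overlapping gene that rose are argued against as a general source, since 5 of 78 genes with annotated exons shared 0.1 or more of their exonic bases with one. With SD36Me, at the same dose and time, none of the 79 genes had a mean above 1.29. The rise was thus seen with SD36 and not with SD36Me, and its mechanism was not tested.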
